A study of Homo sapiens with 6 samples.

How the data were processed

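The series holds 6 RNA-seq libraries of day 5 cardiac progenitor cells derived from the H1 human embryonic stem cell line, 3 read as SORBS2 knockdown and 3 as control. Each library has a file with a gene identifier, a symbol and a value for 26460 genes. The values are FPKM as deposited, fragments per kilobase of gene scaled to the reads of the library, going by the names of the files and the values. The submitters' processing notes name STAR 2.5.0a, HTSeq, DESeq2 and the genome build hg19, and their roles, order, gene annotation and filters are not given in the sources used here. Values summed to 244934 to 251325 FPKM per library. Of the 26460 identifiers, 25399 were found in a table of gene names, and 27 symbols had been turned into dates, so genes were matched by identifier.

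FPKM keeps the trace of whole reads. Values of all 6 libraries were whole reads for 97.5% of tested genes (14436 of 14813), after fitting a gene length and library total. The tolerance was 0.03 reads plus an allowance for rounding of the values, so it was looser for long genes and high counts. The exon length of GENCODE release 29 served for 9642 genes and a searched whole length for 4794. In a trial on 400 genes of known length the search gave the right length for 99.2%. Those genes already gave whole reads at their reference length, and the search started near it. The trial therefore does not show that the lengths searched for the 4794 genes are right. The fit gave library totals of 20060000 to 29850000 reads and a median of 754 reads per tested gene. Such intervals as are given cover counting error only. The mean log2 depth differed by -0.005 between knockdown and control.

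Genes with FPKM of at least 1 in 3 or more libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, two-sided, and Benjamini-Hochberg adjustment over the 14813 genes. A fold change is on the log2(FPKM + 0.5) scale, which understates the change of low genes. Calls are adjusted p under 0.05. The fit had 4 residual degrees of freedom and 4.16 prior ones. For single genes set before the data were examined, exact two-sided permutation tests were run in addition. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

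The comparison, its test, the alternatives and 39 gene lists were set before the data were examined. The lists cover cardiac fields and mesoderm, contractile genes, signalling pathways, other cell types, metabolism, stress and RNA quality. Some genes are in several lists, so list results are not independent of one another. The 36 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over lists. An estimated correlation, fry and a rank form of camera were alternatives, and members were also adjusted over the list alone. The genes of the mitochondrial genome (0 of 13 in the files), replication-dependent histones (4 tested) and skeletal myogenic genes (2 tested) were too few to test as lists.

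The genes named are SORBS2, the 12 largest rises and the 12 largest falls among called genes with a mean FPKM of at least 2 and no overlap between groups, passing over Y-linked genes, XIST, and symbols with set prefixes of unnamed loci and small RNAs. RN7SL1 has none of these prefixes and was kept. Added to these are up to 5 members with the smallest p of each list discussed, and 15 further genes fixed whatever their values. Other genes are said to be named after their values were seen. Some genes that this rule takes are not reported here, though they stay in the tests and counts.

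Alternatives were pseudocounts of 0.1 and 1, no filter or a mean FPKM of at least 5, 3 other scalings, no intensity trend, robust empirical Bayes, array quality weights, a replicate block, other thresholds and leaving out each library in turn. Added after the data were seen were voom in limma on the whole reads, removal of a loess trend (span 0.3) on GC content and length in each library, and list counts without the libraries at the ends of the first principal component.

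The steps were tested on simulated data with 14813 genes, 200 of them changed, in 10 draws. Gene variances were drawn from the prior fitted to the real libraries. Noise was independent between genes, so the draws lack correlated genes and shifts of whole libraries. For this comparison 26.8% of genes changed 1.3-fold, 61.0% of those changed 1.5-fold, 87.2% of those changed 2-fold and 99.0% of those changed 4-fold were called, with a mean of 7.2 false calls per draw. A list was called in 10 of 10 draws when all its members were shifted down by the same amount. In the real data that list, the second heart field, had 9 positive and 21 negative changes. The trial does not show how list calls behave at mixed shifts or other sizes of shift. Nor does it show this where members are correlated, as at the 0.459 estimated for smooth muscle genes. Replicates were compared as reads, and no library pair within a group differed by as little as counting noise, with chi-square per degree of freedom of 6.51 to 15.0. Pairs across groups had 12.5 to 42.5, of which knockdown replicate 1 with control replicates 1 and 2 (12.5 and 14.45) lay within the range inside groups. No library was left out of the comparison.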

Results

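RNA-seq libraries were made from cardiac progenitor cells on day 5 of differentiation of the human embryonic stem cell line H1. The cells had been treated with CHIR99021, an inhibitor of GSK3 that turns on canonical Wnt signalling, from day 0, and with Wnt-C59, which blocks the secretion of Wnt ligands, from day 2. The series sets cells with knockdown of SORBS2, which encodes an adaptor protein of the actin cytoskeleton and cell adhesions, against control cells. No label states outright which library is which. The 3 libraries whose titles start with V_C were read as controls, and the 3 whose titles start with 33_1, 33_8 and 34_11 as knockdown replicates 3, 2 and 1. What these opening numbers stand for is not stated. They differ between the knockdown libraries, while the controls share V_C. Whether the knockdown libraries are replicates of the same condition is therefore not known. Library totals worked out from the values, to the nearest 10000 reads, were 20060000, 23310000 and 29850000 for knockdown replicates 1, 2 and 3, and 29650000, 22410000 and 21200000 for control replicates 1, 2 and 3. Their means were 24410000 reads in knockdown and 24420000 in control. Nothing says that the libraries of a group came from separate differentiations, so p-values measure only the spread between these libraries, which may be technical.

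The first question was whether the targeted transcript was lower in the libraries read as knockdown. SORBS2 (ENSG00000154556) was listed at 1.14, 1.22 and 1.43 FPKM in knockdown replicates 1, 2 and 3 and at 1.68, 1.51 and 1.65 FPKM in control replicates 1, 2 and 3. The means were 1.26 ± 0.148 FPKM in knockdown and 1.61 ± 0.089 FPKM in control (SD, n = 3 each), a ratio of 0.782. Every knockdown value lay under every control value, and an exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 libraries allow. SORBS2 did not pass the test over all genes, with a log2 difference of -0.26 (SE 0.13) and a limma adjusted p of 0.311. These values rest on 1571 reads in knockdown and 1985 in control. The ratio of the read rates was 0.792, with an exact 95% interval of 0.741 to 0.847 that covers counting error only. The groups are called knockdown and control from the titles alone. In the GRCh38 annotation (GENCODE release 29) the gene lies on chromosome 4 from 185585444 to 185956652 on the minus strand, while the submitters' processing notes name hg19. The paralog SORBS3 (23.2 and 22.6 FPKM in knockdown and control, log2 difference 0.04) did not pass the test, with an adjusted p of 0.862.

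**Figure D1:**
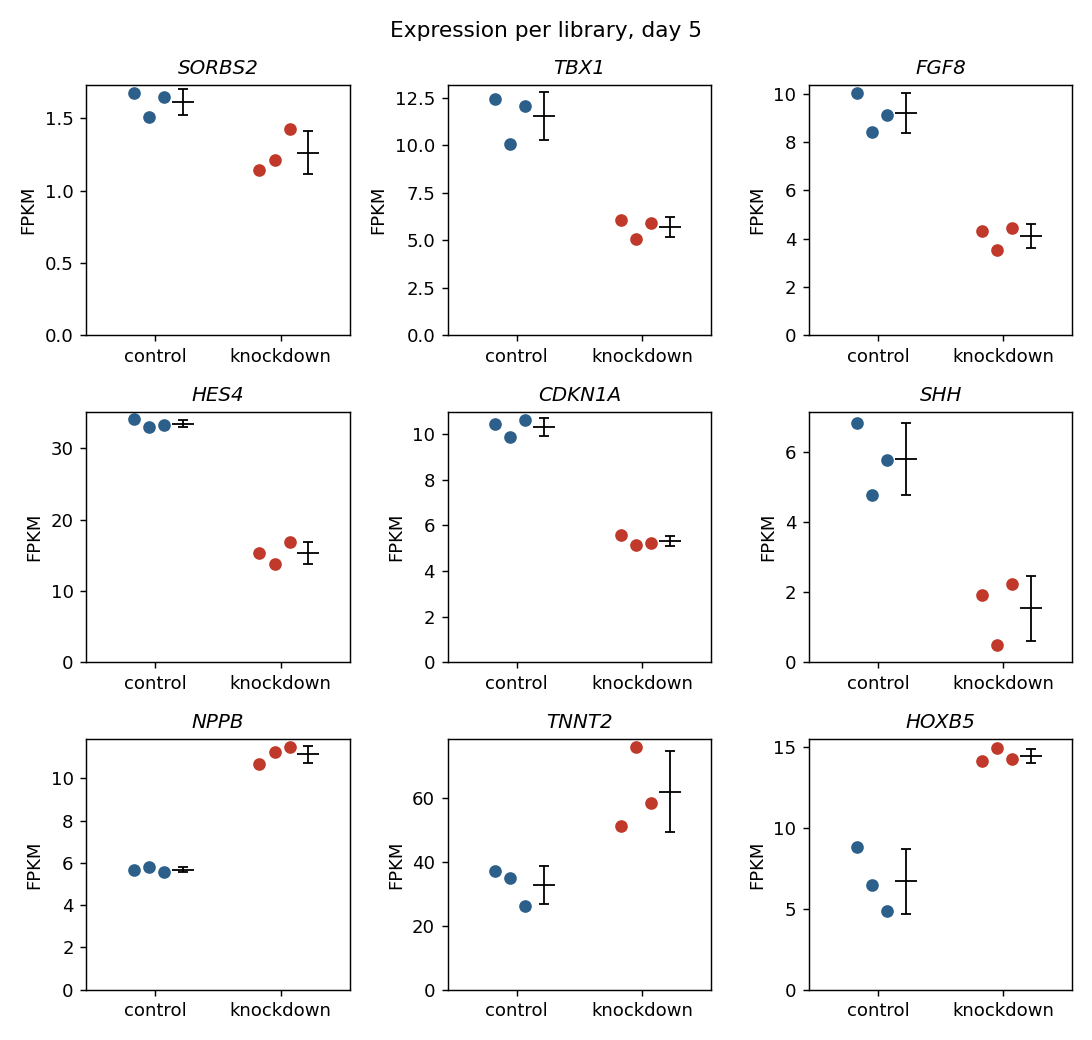
FPKM per library for 9 genes, with controls in blue and knockdown libraries in red, drawn within a group in the order of replicates 1 to 3. The black mark is the mean and its bar the SD (n = 3). SORBS2 means were 1.61 FPKM in control and 1.26 FPKM in knockdown, while TBX1 means were 11.5 and 5.69 FPKM.

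The second question was which mRNAs differed between SORBS2 knockdown and control progenitors. TBX1, a transcription factor of the anterior second heart field, fell from 11.5 ± 1.26 to 5.69 ± 0.531 FPKM (SD, n = 3), and the growth factor gene FGF8 fell from 9.19 ± 0.819 to 4.11 ± 0.486 FPKM. HES4, a transcriptional repressor of the HES family, fell from 33.4 ± 0.526 to 15.3 ± 1.55 FPKM. NPPB, which encodes a natriuretic peptide made by early ventricular muscle, rose from 5.68 ± 0.107 to 11.15 ± 0.404 FPKM, and TNNT2, the cardiac troponin T gene, rose from 32.8 ± 5.88 to 62.1 ± 12.65 FPKM. Of 14813 genes tested, 430 were called at an adjusted p under 0.05 in limma, 180 higher and 250 lower in knockdown. Of these, 73 differed at least 2-fold, 28 higher and 45 lower. The libraries of one group lay entirely above or below those of the other for 26% of tested genes, against 10% by chance. The same held for each of the 430 called genes. These were picked for a small p in the same libraries, so their separation is no added evidence.

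The count of called genes changed when 1 library was left out. It was 668 without knockdown replicate 1, 48 without knockdown replicate 2, 51 without knockdown replicate 3, and 77, 34 and 87 without control replicates 1, 2 and 3. Knockdown replicate 1 lay as near to the controls as to part of its own group, with r across genes of 0.9853 with control replicate 1 and 0.9829 with control replicate 2, against 0.9828 and 0.9871 with knockdown replicates 2 and 3. The 22 genes still called in every one of those fits included FGF8, TBX1, HES4, HEY1, NRARP, CDKN1A, ENC1, IL17RD, NPPB and LUM.

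Among the 12 largest rises were 3 transcripts of the HOXB cluster, which patterns the body axis. HOXB6 rose from 2.27 ± 1.29 to 8.60 ± 1.95 FPKM, HOXB5 from 6.71 ± 2.01 to 14.4 ± 0.456 FPKM and the antisense transcript HOXB-AS3 from 7.25 ± 1.87 to 16.8 ± 1.58 FPKM (SD, n = 3). Strandedness of the libraries is not given in the sources used here, so reads of HOXB-AS3 and of the genes it overlaps cannot be told apart. Transcription factor genes among the rises were PRRX1 (log2 change 1.46), LHX2 (1.28) and TBX4 (1.16). Genes of secreted or matrix proteins were MXRA5 (1.73), LUM (1.34), which encodes the matrix proteoglycan lumican, and RELN (1.28). NODAL, a TGF-beta family ligand of the early embryo, rose by a log2 change of 1.58, with 9.16, 21.01 and 9.46 FPKM in knockdown replicates 1, 2 and 3 and 3.79 ± 0.439 FPKM in control. FAM65C (1.37) and C16orf54 (1.11) completed the group.

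The 12 largest falls held SHH, the Sonic hedgehog ligand gene (log2 change -1.73, with knockdown replicate 2 at 0.494 FPKM against 1.93 and 2.23 FPKM in knockdown replicates 1 and 3), and the transcription factor genes FOXC2 (-1.53) and T, also called brachyury (-1.525). CXCL5 (-1.43), the Wnt receptor gene FZD5 (-1.38), SBK2 (-1.19), TSPEAR-AS1 (-1.16), ENC1 (-1.15), SPOCK3 (-1.15), CYP1B1 (-1.13) and IL17RD (-1.11), an inhibitor of FGF signalling, also fell. The fall of largest size was in RN7SL1, the RNA component of the signal recognition particle, at 571 ± 227 FPKM in control and 115 ± 55.9 FPKM in knockdown. RN7SL1 has near-identical copies in the genome, so its level is uncertain.

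**Figure D2:**
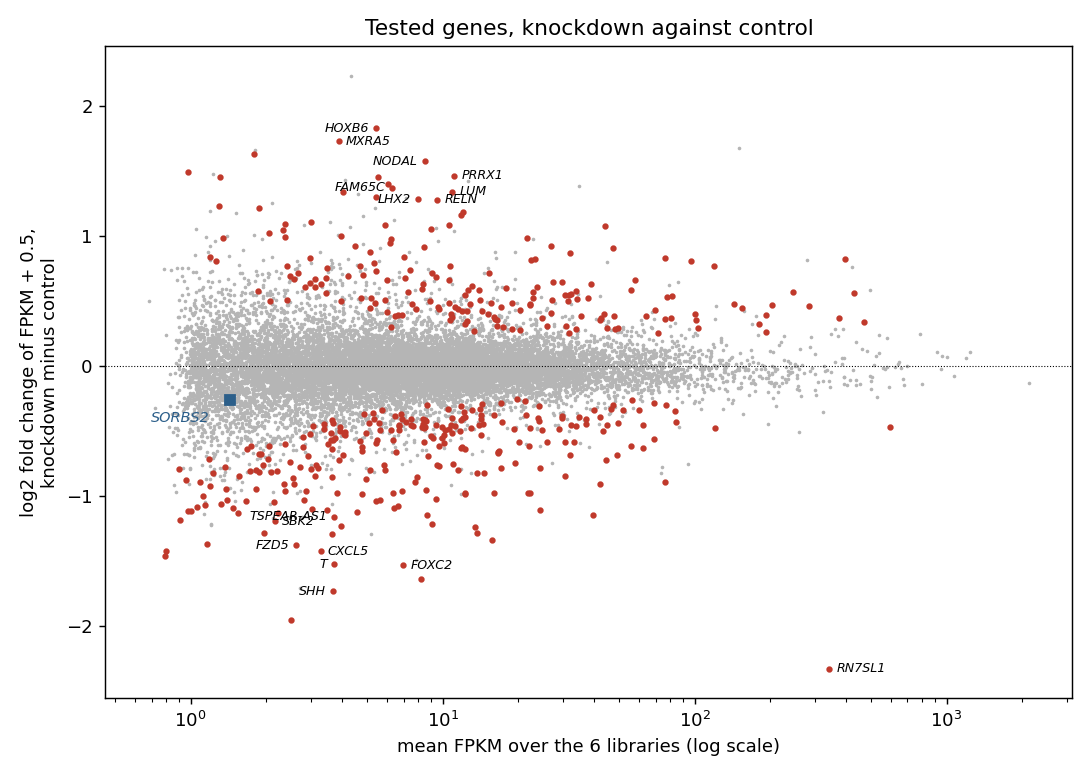
Log2 fold change of FPKM + 0.5 (knockdown minus control) against mean FPKM over the 6 libraries, on a log axis, for the 14813 genes tested. Red points are the 430 genes called at an adjusted p under 0.05, the blue square is SORBS2, and names mark the 8 largest rises and the 8 largest falls among the genes chosen by size.

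Of 30 second heart field genes tested, 8 fell and 1 rose (13 lower and 7 higher when adjusted over the list alone), with camera adjusted p = 0.015 and adjusted p = 0.207 with an estimated correlation. TBX1, FGF8, FOXC1 (16.45 to 8.16 FPKM), FOXC2, CXCR4, BMP7 and ALDH1A2, the retinoic acid synthesis enzyme gene, were among those that fell, whereas SEMA3C, a guidance ligand of the outflow tract, rose from 18.2 to 27.3 FPKM. ISL1, the transcription factor gene most often used to mark this field, was at 35.6 ± 3.06 FPKM in control and 26.7 ± 2.89 FPKM in knockdown and did not pass the test (adjusted p = 0.060). With 1 library left out, 2 to 7 members were called lower and 0 or 1 higher, the fewest without control replicate 2.

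Genes of FGF signalling and its ERK feedback had 6 of 24 tested lower and 1 higher (13 lower and 1 higher adjusted over the list alone, camera adjusted p = 9.0e-07, adjusted p = 0.207 with an estimated correlation). FGF8, ETV5, IL17RD, SPRY4 and SPRY1 fell, of which SPRY1, SPRY4 and IL17RD encode feedback inhibitors and ETV5 a transcription factor induced by the pathway. The one rise was in the receptor gene FGFR2 (45.1 to 71.3 FPKM), named after its values were seen. With 1 library left out, 2 to 5 members were called lower and 0 or 1 higher. Notch pathway genes had 4 members lower and 0 higher of 36 tested (4 and 0 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.362 with an estimated correlation). These 4 were HES4, HEY1 (20.5 to 12.8 FPKM), NRARP (7.72 to 3.52 FPKM) and HEYL (1.85 to 0.881 FPKM), which are known as targets or feedback regulators of the pathway. The receptor gene NOTCH1 was at 10.4 FPKM in control and 10.7 FPKM in knockdown (adjusted p = 0.853). With any 1 library left out 3 Notch members were called, and without knockdown replicate 1 the list was not (camera adjusted p = 0.064).

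In the primitive streak list 5 of 13 tested fell and 1 rose (6 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.026 and adjusted p = 0.518 with an estimated correlation. FGF8, SP5 (10.4 to 5.49 FPKM), GSC, EOMES and T fell and NODAL rose. This call was lost without knockdown replicate 3 (camera adjusted p = 0.184) and without control replicate 1 (0.071), and 1 or 2 members were called lower in each fit with 1 library left out, except 6 without knockdown replicate 1. In the paraxial mesoderm list 3 of 10 fell, FOXC1, FOXC2 and T, and 0 rose (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0076, adjusted p = 0.207 with an estimated correlation), against 0 to 3 lower with 1 library left out. None of these is particular to the list, since FOXC1 and FOXC2 are also second heart field members and T a primitive streak member. Definitive endoderm genes had 3 of 19 lower and 0 higher (9 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.518 with an estimated correlation). The 3 were CDH1 (6.57 to 3.045 FPKM), CXCR4 and PRDM1, and the endoderm factor gene FOXA2 was at 7.46 FPKM in control and 2.92 FPKM in knockdown (adjusted p = 0.081). The endoderm call was lost without knockdown replicate 3 (camera adjusted p = 0.114) and without control replicate 3 (0.239), and 0 or 1 members were called lower in each fit with 1 library left out, except 4 without knockdown replicate 1. Of 15 tested pluripotency genes, 2 fell, CDH1 among them, and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.372 with an estimated correlation), against 0 to 3 lower with 1 library left out. POU5F1 was under the expression filter, at 1.63, 0.716 and 0.967 FPKM in knockdown replicates 1, 2 and 3 and at 0.938, 1.43 and 0.886 FPKM in control replicates 1, 2 and 3.

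SHH, the hedgehog target gene GLI1 (2.46 to 1.34 FPKM), FOXF1 and FOXL1 fell, and 0 of 22 tested members of the hedgehog pathway list rose (5 lower and 5 higher adjusted over the list alone). The list had a median log2 change of 0.08 and a mean of -0.095, and was not called (camera adjusted p = 0.351). The receptor gene PTCH1 was at 12.6 ± 1.77 FPKM in control and 8.98 ± 1.02 FPKM in knockdown (adjusted p = 0.075). Targets of canonical Wnt signalling had 5 of 21 lower, SP5, CCND1, NKD2, SFRP1 and T, and 0 higher (7 lower and 4 higher adjusted over the list alone), and the list was not called (camera adjusted p = 0.409). Without knockdown replicate 1 the hedgehog list had 2 members higher and 5 lower and the Wnt list 5 lower, and in the other 5 fits with 1 library left out each had 0 higher and 0 or 1 lower.

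In the sarcomere list 4 of 34 tested rose and 3 fell (9 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.0076 and adjusted p = 0.518 with an estimated correlation. The atrial light chain gene MYL7 rose from 347 to 512 FPKM, the cardiac actin gene ACTC1 from 54.5 to 98.3 FPKM, and TNNT2 and MYL9 rose too. TNNT1, the troponin T of slow skeletal muscle, fell from 13.95 to 8.14 FPKM, as did ANKRD1 (39.6 to 24.2 FPKM) and PDLIM1, the last named after its values were seen. Without knockdown replicate 1, 8 sarcomere genes were called higher and 3 lower, and 0 higher and 0 or 1 lower with any other library left out. Without knockdown replicate 2 the list was not called (camera adjusted p = 0.085). Smooth muscle genes had 4 of 16 higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 2.6e-06, adjusted p = 0.372 with an estimated correlation). These were TAGLN (27.1 to 40.8 FPKM), CSRP1 (4.08 to 8.29 FPKM), MYL9 and PDLIM7. Without knockdown replicate 1, 6 were called, without control replicate 2, 0, and 1 with any other library left out.

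First heart field genes had 2 of 8 higher, NPPB and HAND1 (170 ± 12.25 to 236 ± 22.6 FPKM), and 0 lower (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.372 with an estimated correlation). The median log2 change of this list was 0.29 and its mean 0.03. NKX2-5, an early cardiac transcription factor gene, was at 2.95, 3.92 and 6.06 FPKM in control replicates 1, 2 and 3 and at 0.357, 2.44 and 0.640 FPKM in knockdown replicates 1, 2 and 3 (log2 difference -1.71, SE 0.43, adjusted p = 0.079). It was called lower without knockdown replicate 2 (log2 change -2.231, adjusted p = 0.026) and with voom (-2.241, adjusted p = 0.016). The list then had 1 member higher and 1 lower without knockdown replicate 2, 3 higher and 1 lower with voom, 2 higher without knockdown replicate 1, and 1 higher with any other library left out. Without knockdown replicate 2 the list was not called (camera adjusted p = 0.083). In the cardiac mesoderm list KDR, the VEGF receptor gene, and HAND1 rose, and CXCR4, EOMES and FOXF1 fell, of 17 tested (8 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.483 with an estimated correlation). Camera called the list as higher, with 12 positive and 5 negative changes, a median log2 change of 0.22 and a mean of 0.006. That call was lost without knockdown replicate 1 (camera adjusted p = 0.058) and without control replicate 2 (0.101), and 0 members were called in 5 of the 6 fits with 1 library left out.

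Cardiac transcription factors moved both ways. HAND1, PRDM6 and ZFPM2 rose and TBX1, HEY1 and IRX5, the last named after its values were seen, fell among 34 tested (8 higher and 8 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.596). GATA4 (60.2 and 74.4 FPKM in control and knockdown, adjusted p = 0.077), HAND2 (52.1 and 50.45 FPKM, adjusted p = 0.809), MEF2C (6.40 and 5.36 FPKM, adjusted p = 0.283) and TBX5 (1.745 and 1.15 FPKM, adjusted p = 0.327) did not pass the test. With 1 library left out, 0 transcription factors of this list were called higher and 2 or 3 lower, except 4 higher and 3 lower without knockdown replicate 1.

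Of 6 HOX genes tested HOXB2, HOXB3, HOXB5 and HOXB6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.207 with an estimated correlation). Control replicate 3 lay apart for HOXB6, at 0.833 FPKM against 3.35 and 2.62 FPKM in control replicates 1 and 2, and for HOXB4, at 7.76 against 18.2 and 16.2 FPKM. Without control replicate 3, 2 members were called higher and the median log2 change of the list was 0.48, against 0.71 with all libraries. Without control replicate 1, 2 members were called, and without knockdown replicate 2, knockdown replicate 3 or control replicate 2, 0 were. Without knockdown replicate 2 the list still was called (camera adjusted p = 1.3e-06). Mesenchyme and matrix genes had 5 of 36 higher and 3 lower (11 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.372 with an estimated correlation). LUM, SPARC, COL1A1 (325 to 420 FPKM), COL1A2 and THY1 rose, and COL4A2, FN1 (697 to 502 FPKM) and FBN2 fell, of which COL1A2, FN1 and FBN2 were named after their values were seen. Control replicate 3 lay apart in this list too, for COL3A1 at 37.1 FPKM against 101 and 79.5 FPKM in control replicates 1 and 2, and for COL6A3 at 3.46 against 9.24 and 7.54 FPKM. Neither passed the test (adjusted p = 0.068 for COL3A1 and 0.082 for COL6A3), and COL3A1 and COL6A3 were named after their values were seen. The call was lost without knockdown replicate 2 (camera adjusted p = 0.1001) and without control replicate 2 (0.0525). Without knockdown replicate 1, 8 matrix genes were called higher and 1 lower, and 1 or 2 higher and 0 lower with any other library left out.

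Of the SORBS family and its binding partners, the talin gene TLN2 rose from 9.41 to 12.4 FPKM and 0 of 34 tested fell (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.362 with an estimated correlation). In the cytoskeleton and adhesion list TAGLN rose and ANKRD1 and TAGLN2 fell of 43 tested (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.579 with an estimated correlation). Camera called this list as higher, with 28 positive and 15 negative changes and a median log2 change of 0.06. The call for the SORBS partners was lost without knockdown replicate 2 (camera adjusted p = 0.086), control replicate 1 (0.088) or control replicate 2 (0.057), and that for the cytoskeleton without knockdown replicate 2 (0.186) or control replicate 1 (0.167). In the 6 fits with 1 library left out, 0 to 2 SORBS partners were called higher, and 0 to 3 cytoskeleton genes higher and 0 to 2 lower.

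**Figure D3:**
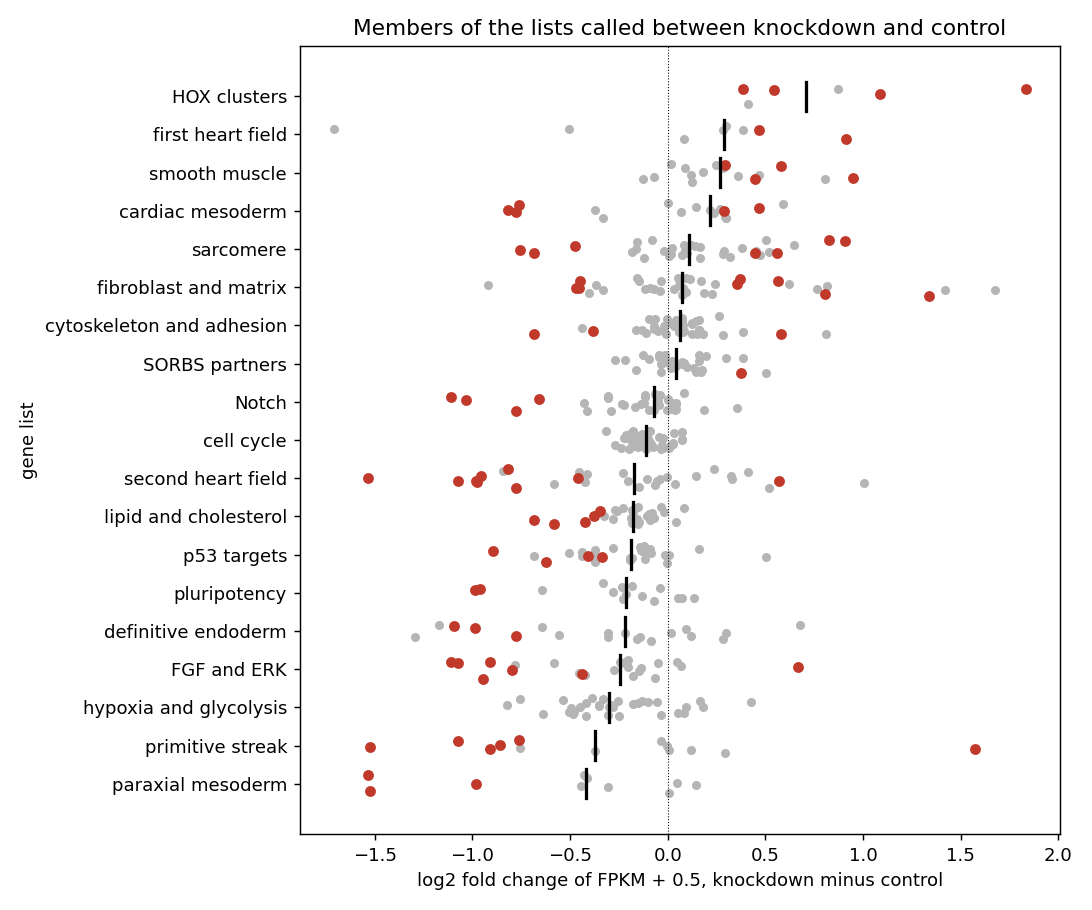
Log2 fold change of FPKM + 0.5 (knockdown minus control) for each tested member of the 19 gene lists called by camera, with called members in red, others in grey and the list median as a black bar. Medians run from -0.42 in paraxial mesoderm to 0.71 in the HOX list.

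In the cholesterol and fatty acid synthesis list 5 of 29 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 2.9e-07, adjusted p = 0.207 with an estimated correlation). STARD4, SC5D (31.35 to 20.7 FPKM), DHCR7 and SCD (94.1 to 73.8 FPKM) were among those that fell. Without knockdown replicate 1, 7 were called lower, and 0 with any other library left out. Among p53 targets CDKN1A, the p21 cell cycle inhibitor gene, fell from 10.3 ± 0.385 to 5.31 ± 0.224 FPKM, and BTG2, BAX and RRM2B fell too, with 0 of 28 higher (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.156 with an estimated correlation). With 1 library left out, 1 to 4 p53 targets were called lower. The hypoxia and glycolysis list was called lower with 0 of 33 members called by limma, while 20 were lower and 2 higher at an unadjusted p under 0.05. Of 32 members tested by voom, 13 were called lower and 1 higher (18 lower and 1 higher in limma adjusted over the list alone, camera adjusted p = 5.4e-05, adjusted p = 0.518 with an estimated correlation). Without knockdown replicate 1, 11 members were called lower, and 0 with any other library left out. PGK1 was at 58.6 FPKM in control and 44.9 FPKM in knockdown (adjusted p = 0.060). The cell cycle list was called lower with 0 of 47 members called by limma and 0 of 46 by voom. At an unadjusted p under 0.05, 5 were lower and 0 higher, with a median log2 change of -0.11 (0 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.394 with an estimated correlation). Without knockdown replicate 3 it was not called (camera adjusted p = 0.053), and without knockdown replicate 1, 5 members were called lower. With an estimated correlation 0 of the 36 lists were called, 6 had an unadjusted p under 0.05, fry called 8 and the rank form of camera 13. Other settings ended some calls, at a camera adjusted p of 0.285 for the endoderm and paraxial mesoderm lists and 0.163 for the primitive streak list with a mean FPKM of at least 5, and of 0.083 for the second heart field and 0.090 for cardiac mesoderm with no filter on low values. Removing a trend on GC content and length ended those of the matrix (0.125), SORBS partner (0.153) and cytoskeleton (0.066) lists, while the mean FPKM filter brought in the hedgehog list as higher (0.012) and ion channels as lower (0.032).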

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

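The voom and GC content alternatives were chosen after seeing the data. The 430 called genes (180 higher, 250 lower) became 18 (5 higher, 13 lower) with no filter on low values, 143 (44, 99) with no intensity trend, and 1012 (475, 537) with voom on whole reads, of which 394 were shared. They became 73 (28, 45) with a 2-fold limit, 19 (5, 14) at an adjusted p under 0.01 and 1024 (476, 548) at one under 0.1. With the replicate block there were 200 (74, 126), 176 of them shared. The same numbers did not deviate together (correlations of deviations -0.077, 0.015 and -0.104 for replicates 1, 2 and 3). The labels do not say whether equal numbers mark a shared culture or batch, and so few libraries cannot exclude pairing. Leaving out 1 library gave 34 to 668 calls, 7 to 298 higher and 27 to 370 lower, and the cause beyond fewer samples was not tested. The other scalings gave 413 to 451 calls and moved the share of higher calls from 41.9% to between 44.1% and 47.2%. With the GC content and length trend removed 438 were called. SORBS2 stayed between -0.34 and -0.21 on the log2 scale and was called under none of 18 alternatives (adjusted p 0.067 to 0.530). Of the 36 lists, 19 were called, 0 with an estimated correlation and 8 with fry, and 14 to 19 without 1 library. Genes not called in the main fit but called lower elsewhere were ISL1 (adjusted p 0.047 with a mean FPKM of at least 5, 0.045 with the replicate block and 0.015 with voom), PTCH1 (0.046 with array quality weights, 0.046 without knockdown replicate 1 and 0.013 with voom) and NKX2-5 (0.026 without knockdown replicate 2 and 0.016 with voom), and GATA4 was called higher with voom (0.025). FOXA2 and PGK1 were called lower with voom, with array quality weights and without knockdown replicate 1, and PGK1 also with a mean FPKM of at least 5 and with shares of summed FPKM. No called gene that is named turned its direction, and of called lists only the paraxial mesoderm median did (0.008 with a mean FPKM of at least 5). Genes near 0 that did when 1 library was left out were HAND2 (-0.155 to 0.038, above 0 without knockdown replicate 3), NOTCH1 (-0.024 to 0.123, under 0 without knockdown replicate 2 at -0.024 and control replicate 3 at -0.002, and -0.009 with the GC content trend removed) and SORBS3 (-0.058 to 0.099, with -0.020 without knockdown replicate 1). The cause was not tested. Depth limits low genes, since 1 read on 1 kb is worth 0.034 to 0.050 FPKM.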

Other observations

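Other lists held single changes without a call for the list. In the BMP and TGF-beta list 7 of 36 tested fell and 2 rose (11 lower and 7 higher adjusted over the list alone, camera adjusted p = 0.434). Of BMP targets, ID3 (140 to 101 FPKM), ID1 (76.1 to 48.8 FPKM) and ID4 (29.8 to 14.7 FPKM) fell. BMP7 fell too, and TGFBI rose. Other members were higher in knockdown without passing the test. Among them were ID2 (73.5 and 93.15 FPKM in control and knockdown, limma adjusted p = 0.089) and MSX1 (44.3 and 67.55 FPKM, 0.051). ID2 was named after its values were seen. Fits with 1 library left out called 1 or 2 members lower and 0 or 1 higher, except 6 lower and 4 higher without knockdown replicate 1. Among congenital heart disease genes 6 of 46 rose and 4 fell (8 and 11 adjusted over the list alone, camera adjusted p = 0.8965, median log2 change 0.001 and mean -0.08), with TBX1, FOXC1 and FOXC2 among those lower and PRDM6 among those higher. The calls were 7 higher and 5 lower without knockdown replicate 1, 1 and 4 without knockdown replicate 2, and 0 higher and 2 or 3 lower with any other library left out. In the retinoic acid list HOXB5, HOXB3 and STRA6 rose and ALDH1A2 fell of 19 (6 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.351). Left-out fits called 0 to 2 of them higher, with 0 without knockdown replicate 2, knockdown replicate 3 or control replicate 2, and 1 lower without knockdown replicate 1 or 3 and 0 otherwise. BST2 rose from 16.6 to 29.9 FPKM and 1 member fell among 21 interferon response genes (5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.887, with a median of -0.03 against a test direction of up). BAG3 and JUN rose and XBP1 fell among 27 stress genes (4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.788, median -0.03 and mean 0.02). Each of the interferon and stress lists had 0 or 1 members called higher and 0 or 1 lower with 1 library left out.

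KDR rose among 11 endothelial genes (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.265), BNC2 rose and ALDH1A2 fell among 7 epicardial genes (2 and 1, camera adjusted p = 0.351), and HAND1 rose among 7 extraembryonic genes (1 and 2, camera adjusted p = 0.870). The endothelial list had 2 positive and 9 negative changes and the extraembryonic list 3 and 4, each with a median log2 change of -0.155. LHX2 rose among 11 neural genes (1 and 1, camera adjusted p = 0.477). ETS1 rose and 2 members fell, SOX9 among them, of 10 neural crest genes (4 and 3, camera adjusted p = 0.424, median 0.115 and mean -0.03). Without knockdown replicate 2, knockdown replicate 3, control replicate 1 or control replicate 3, 0 neural crest genes were called, and without control replicate 2, 1 was, lower. The endothelial, extraembryonic and neural lists had 0 calls with any library but knockdown replicate 1 left out, and the epicardial list 0 without control replicate 2 and 1 with any other left out. By limma 0 members were called among 21 ion channel genes (3 higher and 7 lower at an unadjusted p under 0.05, 3 and 2 of 20 by voom, 3 and 4 adjusted over the list alone, camera adjusted p = 0.602, median -0.055 and mean 0.05). Likewise 0 were called among 29 non-canonical Wnt genes (4 and 5 at an unadjusted p under 0.05, 3 and 5 by voom, 3 and 2 adjusted over the list alone, camera adjusted p = 0.8965, median -0.03 against a test direction of up). Also 0 were called among 36 oxidative phosphorylation genes (1 and 6 at an unadjusted p under 0.05, 0 and 1 by voom, 0 adjusted over the list alone, camera adjusted p = 0.387) and 73 ribosomal protein genes (0 and 2, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 0.249). The ribosomal list was called lower without knockdown replicate 3 (camera adjusted p = 0.0068) or control replicate 3 (0.0038). Control replicate 3 was at least 2-fold under every other library for 13 genes and over every other for 1. Knockdown replicate 2 was so far under the others for 6 genes and over them for 2, NODAL being one of these, and knockdown replicate 3 under them for 1. Only knockdown replicate 1 has title number 34. A comparison of title numbers was run, but with 1 library on one side it cannot separate title number from library. No conclusion is drawn from it.

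The tests of splits, of GC content and of left-out libraries were chosen only after the results were seen, and the test of control differences and that of structured RNAs before. Of the 10 splits of the 6 libraries into 3 and 3, only the real one gave as many as 430 genes, so 1 split in 10, and the highest other gave 0 by limma (932 genes at an unadjusted p under 0.05, against 2963). Too few splits exist for a share under 0.05. Every other split mixes libraries of both groups, so any group difference enters its residual spread and lowers its count. The counts of the other splits are therefore not the level expected without a group difference. Removing the GC content and length trend left 89.3% of the called genes that have both values called, which argues against that bias as the whole cause. Genes at p under 0.01 in 4 libraries were followed in the left-out knockdown and control library. They kept their sign in 80.1% to 83.3% of cases for knockdown replicate 1 and 87.6% to 93.4% for the others. Changes private to 1 kept library seldom pass such a screen, and these genes are not the 430 called ones. The percentages therefore show a shared direction for the genes picked. They do not settle how many of the 430 calls are private to single knockdown libraries.

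A candidate explanation that stays open for part of the 430 genes is that the groups differ along an axis on which control cultures also differ. Across all tested genes, which are not independent replicates, the difference of control replicates 1 and 3 correlated with that of the knockdown mean and control replicate 2 at r = 0.132, the highest of 3 rotations, where the prediction needed over 0.3 in 2 of them or under 0.1 in all. The others were 0.114 and 0.020. Over the called genes alone, a set not named in the prediction, r was 0.496, 0.450 and 0.107, and the first 2 of these are differences from control replicate 3. SORBS2 knockdown, the biological explanation that the design names, was not tested apart from it.

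The fall of RN7SL1 (log2 change -2.33) may come from library preparation that carried over structured RNA unequally. The other 9 tested small structured RNAs had a median log2 change of -0.09 (quartiles -0.25 and 0.23), above the bound of -0.2 set for an unaffected class, but their lower quartile passes that bound. Many snoRNA reads can come from their host genes, and no biological explanation was tested. The quartile was looked at only after the result was seen. Unequal carry-over and a change in the cells cannot be told apart here.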
